A study of Mus musculus with 10 samples.

How the data were processed

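Efferent ductules of 10 mice aged 4 months, 5 with Villin-Cre and both alleles of Arl13b floxed (cKO) and 5 with Villin-Cre and 1 floxed allele (control), were profiled by sequencing of total RNA. Per the labels' protocols, RNA was extracted with RNeasy Mini columns and libraries were made with the NEBNext Ultra II directional kit. The genotype groups were taken from the labels, and each library came from 1 mouse.

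The deposited table of estimated counts per gene was made from sequencing reads with tools among which the submitters' processing notes name kallisto 0.46.2, fastp 0.20.0, FastQC 0.11.8 and MultiQC 1.8, without a role or an order. The deposited TPM table gives TPM values for the same genes, with no further normalisation stated by the authors. The transcript annotation, the genome build and the strand setting of the counting are not given in the sources used here. The tables hold 36727 features, of which 35869 (97.7%) have their identifier in GENCODE M21 on GRCm38, the annotation from which positions and overlaps were taken. In 454 cases a symbol belongs to more than 1 identifier, and 316 features repeat the values of another identifier of the same symbol in every library (1.55 to 3.49% of the counts of a library). Of the repeated features 183 were tested and 2 were called, which leaves 385 distinct genes among those called.

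Of the estimated counts, 38.6% were not whole numbers, and all were rounded. Genes were filtered with filterByExpr, scaled by trimmed means of M values, and tested with edgeR 4.0.16 (quasi-likelihood F test, cKO against control, all 10 libraries, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. In all, 17552 genes were tested. CPM values of single genes use the same scaling factors. CPM summed over a list were taken from library totals without these factors, which ran from 0.8602 (control 5) to 1.0546 (cKO 1). Scores are means of log2 CPM with a prior count of 2. Values are given as mean ± SD over libraries, and log2 fold changes with their SE. Ratios of pooled counts have 95% intervals that cover counting error only. Library measures, scores and principal components were compared by two-sided exact permutation tests over all 252 assignments of 5 against 5, for which the smallest p is 0.00794. With library totals from 9.01 to 39.5 M estimated counts (median 21.7 M), the biological coefficient of variation was 0.308.

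Gene groups were tested with camera (limma 3.58.1, preset inter-gene correlation of 0.01, Benjamini-Hochberg adjustment over 31 lists), with camera using an estimated correlation, and with fry, which tests whether a list's genes move one way on balance and does not compare the list with other genes. The lists covered motile cilia, primary cilium, hedgehog pathway, tubulin modification, ion and water transport, brush border, endocytosis and lysosome, steroid receptors, junctions, cytokines, interferon response, complement, macrophages, T and NK cells, B and plasma cells, granulocytes and mast cells, extracellular matrix, smooth muscle, endothelium, adipocytes, epididymis, germ cells, Sertoli and Leydig cells, cell cycle, epithelial injury, Wnt and planar polarity, glutathione, nuclear and mitochondrially encoded respiratory chain, blood and early response genes. The genes named were Arl13b and Vil1, the 12 largest changes in each direction among called genes, and up to 4 members of each list. The largest changes were taken from genes without overlap of the groups, with at least 1 CPM in the higher group and a symbol that is not a clone name. List members were those of smallest p, or the 2 of highest expression where none was called. The named genes also included Esr1, Slc9a3, Aqp1, Aqp9, Car2, Cftr, Lrp2, Cubn, Foxj1, Gli1 and Ptch1. The test, the lists, this rule and 21 alternatives were fixed before the data were examined, and 7 alternatives were added afterwards.

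The alternatives concerned scaling (DESeq2 size factors, upper quartiles, library totals alone), filters, count models (DESeq2 1.42.0, limma voom with and without sample weights, robust empirical Bayes), the TPM values with pseudocounts of 1 and 0.1 and with or without a filter of 1 TPM in 5 libraries, unrounded counts, the replicate number as a block, and the series of animal numbers (below 2900 or not) as a covariate or restricted to the lower series. They also concerned 1 surrogate variable (sva 3.50.0), a test against a fold of 1.5, a threshold of 0.01, leaving out each library in turn, and leaving out the epididymal, germ cell and blood genes. Those added afterwards were leaving out pairs of libraries (control 5 with cKO 5, control 1 with cKO 5), germ cell or macrophage scores as covariates, leaving out pseudogenes with Lars2 and Gm20594, scaling the TPM values by trimmed means, and leaving out repeated features.

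The tests were tested on simulated counts with the means and totals of these libraries, in which 199 of 17361 tested genes were changed. The changed genes were drawn only from those above a minimum mean count, and each gene was simulated independently of the others. edgeR recovered 29.9% of 1.5-fold, 67.2% of 2-fold and 92.3% of 4-fold changes with 9 false calls. DESeq2 recovered 50.7%, 82.1% and 93.8% with 47 false calls, and limma voom 34.3%, 73.1% and 90.8% with 7. R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used. No library was left out of the main comparison.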

Results

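Total RNA was sequenced from whole efferent ductules, the tubules that carry fluid and sperm from the rete testis to the epididymis and are lined by multiciliated and absorptive cells. The 10 libraries came from 10 different mice aged 4 months, 5 conditional knockout (cKO) and 5 control. Both groups carried Villin-Cre, a recombinase driven by the promoter of the brush border gene Vil1. In cKO mice both alleles of Arl13b, a small GTPase of the ciliary membrane, were floxed (flanked by recombination sites), and in controls 1 allele was. Control libraries 1 to 5 held 24.2, 21.9, 32.0, 15.2 and 9.01 M estimated counts (M, mega), and cKO libraries 1 to 5 held 16.1, 21.6, 39.5, 25.0 and 18.2 M. Mean totals of 24.1 ± 9.27 M (SD, n = 5) in cKO and 20.4 ± 8.76 M (SD, n = 5) in control did not differ beyond the spread between libraries (exact permutation test, two-sided, p = 0.532).

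Arl13b, the targeted gene (ENSMUSG00000022911, chromosome 16, 62793685 to 62847040, minus strand), was measured at 21.3, 23.6, 27.9, 25.6 and 27.1 CPM (normalised counts scaled to a common library size) in control libraries 1 to 5 and at 26.2, 27.4, 23.2, 25.3 and 27.8 in cKO libraries 1 to 5. Its means were 26.0 ± 1.84 in cKO and 25.1 ± 2.68 in control (SD, n = 5), a log2 fold change of 0.05 ± 0.09 (SE), and the difference was not past the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.786). Positions are those of GENCODE M21 on GRCm38, and the authors' build is not given in the sources used here. Gene totals do not show the deleted exon, and cells without Villin-Cre keep their Arl13b, so this value does not check the genotype labels. Vil1, which bundles actin in microvilli and whose promoter drives the recombinase (ENSMUSG00000026175, chromosome 1, 74409376 to 74435559, plus strand), fell by 0.72 ± 0.12 on the log2 scale (SE), from 136 ± 13.6 to 82.5 ± 13.6 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.0226).

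The comparison of genotypes addressed what the loss of Arl13b changes in the transcripts of the ductules. In cKO ductules, several transcripts of the absorptive epithelium fell, among them the water channel Aqp1 (759 ± 163 against 1185 ± 47.6 CPM, SD, n = 5). The steroid 5-alpha reductase Srd5a2 also fell (49.0 ± 5.90 against 113 ± 22.7). All 43 measured nuclear genes of the respiratory chain had lower estimates in cKO, and 15 of them fell, although on unscaled TPM values the median of these 43 was 0.02, -0.18 relative to all genes. The claudin Cldn4 (23.7 ± 6.98 against 3.33 ± 0.75) rose, as did the keratin Krt7 (20.8 ± 6.77 against 6.27 ± 1.27). Of 17552 genes tested, 387 passed an adjusted p of 0.05 (edgeR, Benjamini-Hochberg), 104 higher and 283 lower in cKO, and 3714 had an unadjusted p under 0.05. The 5 cKO libraries lay all above or all below the 5 controls for 98 of the higher and 264 of the lower genes. These genes were chosen by their p in the same libraries, so their separation is not further evidence. Over all tested genes separation held for 5.90%, against an expectation of 0.794% by chance. How far that share varies between relabellings was not computed. At least 2-fold changes were found for 52 higher and 44 lower genes.

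The number of genes past the threshold moved when single libraries were left out. It was 1869 without control 1, 30, 41, 22 and 38 without controls 2 to 5 in turn, and 104, 39, 115, 199 and 153 without cKO 1 to 5. Of the 387 called genes, 386 were tested in all 10 of these fits. All 386 kept their sign and an unadjusted p under 0.05 (edgeR), although these fits share most libraries with the one that chose the genes. Among the animals, 2 control and 4 cKO had identification numbers below 2900, and 3 control and 1 cKO above, although the labels do not say that the numbers mark a cohort. With this number series as a covariate 165 genes passed (69 higher, 96 lower), and in the 6 animals below 2900 alone edgeR with Benjamini-Hochberg adjustment called 0 genes, with 1203 at an unadjusted p under 0.05, 162 by DESeq2 and 0 by limma voom. All 387 called genes kept their sign in these 6 animals, and the median ratio of their log2 fold changes to those of all libraries was 0.82. The 6 animals are part of the 10 that chose these genes. The share of higher genes, 26.9%, was 56% (70 higher, 55 lower) when libraries were scaled by their totals alone and 96% (24 higher, 1 lower) on unscaled TPM values with a pseudocount of 1. Unscaled TPM moved the median log2 fold change of all genes to 0.20, and with trimmed-mean scaling of the same TPM values the split was 45 higher and 144 lower.

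The 12 genes with the largest increases were Htr3a, Muc15, Arg1, Gpnmb, Cldn4, Muc20, Prph, Fgfbp1, Vtcn1, H2-Eb2, Snap91 and Sorcs1, with log2 fold changes between 2.12 and 6.30. Cldn4 (chromosome 5, 134945119 to 134946934, minus strand) rose by 2.84 ± 0.23 on the log2 scale (SE; edgeR, Benjamini-Hochberg adjusted p = 0.0014). Htr3a, a subunit of the serotonin-gated channel (chromosome 9, 48899213 to 48911099, minus strand), had 399 counts in the cKO libraries together and 4 in the controls, 2 of which had none. The ratio of pooled CPM was 84.7 (95% counting interval 32.8 to 312; edgeR, Benjamini-Hochberg adjusted p = 0.00457). The interval covers counting error only. Arg1, the arginase of the urea cycle and of alternatively activated macrophages, had 800 pooled counts in cKO and 26 in control, a ratio of 26.1 (17.7 to 40.2). Snap91, a clathrin assembly protein of synapses, rose by 2.38 ± 0.28 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.00907), and Prph, an intermediate filament of peripheral neurons, by 2.71 ± 0.45 (adjusted p = 0.0228). Gpnmb, a glycoprotein of lysosome-rich macrophages, measured 102 ± 65.0 against 7.99 ± 10.1 CPM (adjusted p = 0.0464), with control 1 at 25.9 and the other controls between 1.94 and 5.27. The 2 mucins Muc15 and Muc20 lie over Ano3 and Muc4 on the opposite strand, and the strand setting of the counting is not given in the sources used here, so their source is uncertain. Htr3a (over Gm32335), Sorcs1 (over 3 genes) and Krt7 (over Gm671) also overlap genes on the opposite strand, so the same doubt holds for them. Muc15 was at 23.9 and 50.1 CPM in cKO 2 and cKO 5 and between 0.65 and 7.88 in the other cKO libraries. Adam7, a marker of the epididymis, was highest in the same pair, at 377 and 867 CPM, and summed epididymal transcripts were 699 and 7468 there. The sums were taken from library totals without the scaling factors, the Adam7 values with them. Cldn4, Htr3a and Snap91 were called in all 10 fits without 1 library.

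The 12 genes with the largest decreases were Klk1b21, Dcc, Lad1, Ttr, Klk1b27, Erich4, Rbp2, Slc16a14, Aqp2, Bcat1, Glod5 and Pcp4, with log2 fold changes between -2.43 and -1.48. Lad1, an anchoring filament protein of the basement membrane (chromosome 1, 135818598 to 135833342, plus strand), had the smallest p of all genes and fell by 1.79 ± 0.13 on the log2 scale (SE), from 57.5 ± 9.39 to 16.6 ± 2.21 CPM (edgeR, Benjamini-Hochberg adjusted p = 7.91e-04). Dcc, the netrin receptor, fell by 2.22 ± 0.42 (adjusted p = 0.032), and Ttr, the carrier of thyroxine and retinol-binding protein, by 1.79 ± 0.40 (adjusted p = 0.0497), both in edgeR with Benjamini-Hochberg adjustment. Rbp2, the cellular retinol-binding protein of absorptive enterocytes, was at 8.31 ± 1.49 against 26.3 ± 10.4 CPM. Slc16a14, a monocarboxylate transporter family member, was at 5.58 ± 0.94 against 16.9 ± 5.01, and Bcat1, the cytosolic branched-chain aminotransferase, at 76.7 ± 13.6 against 217 ± 77.9. Klk1b21 and Klk1b27 belong to a family of near-identical kallikrein genes whose reads the counting could have split, and their values are uncertain. Of the 24 genes with the largest changes, 8 overlap another annotated gene, 5 of them on the opposite strand.

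**Figure D1:**
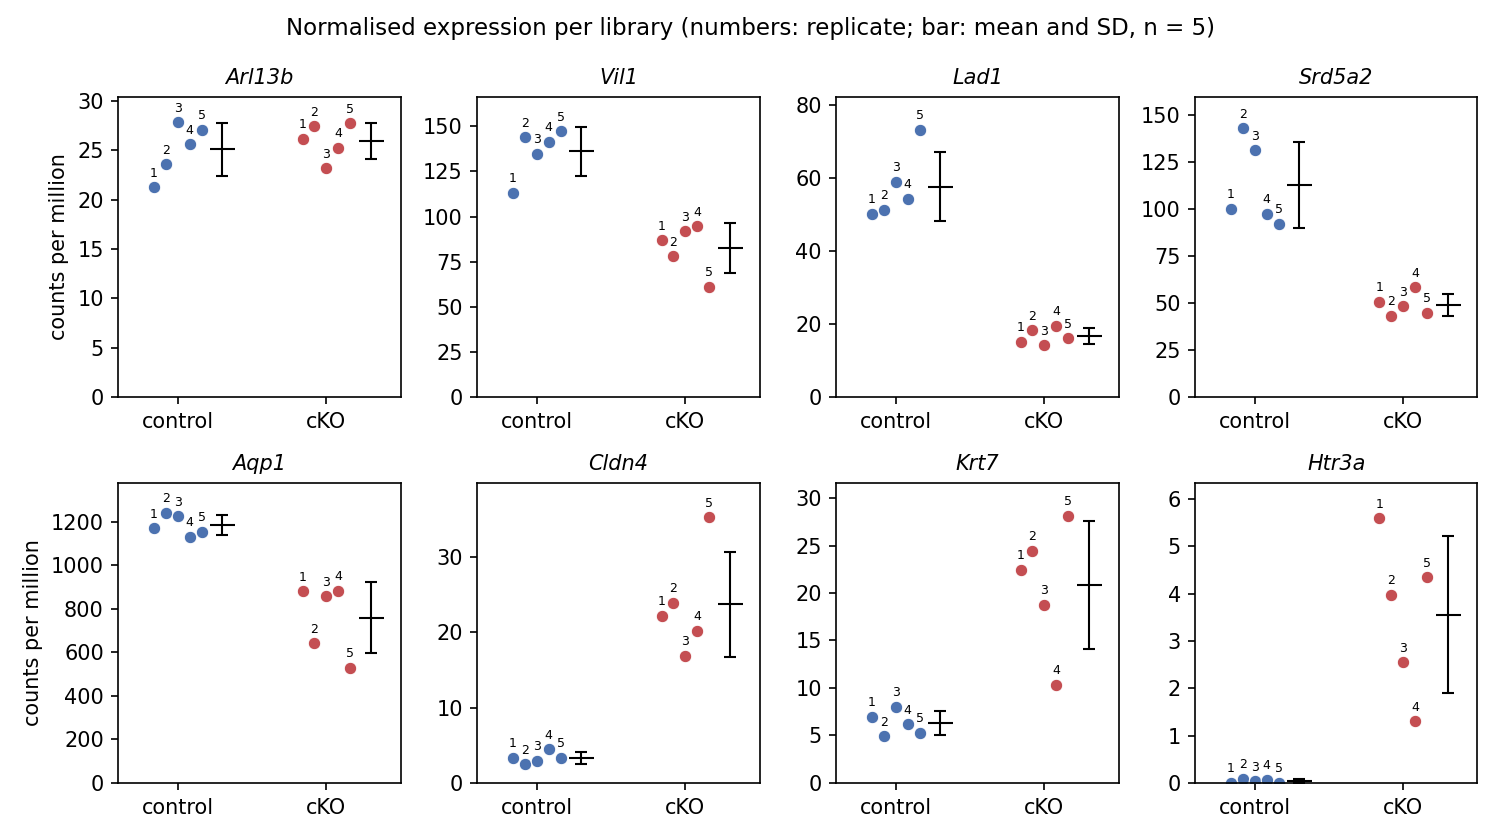
Normalised expression in CPM (vertical axes) of 8 genes in each control (blue) and cKO (red) library, with the replicate number above each point and the mean and SD of 5 libraries beside each group. Arl13b overlaps between the groups, Vil1, Lad1, Srd5a2 and Aqp1 are lower in all 5 cKO libraries than in any control, and Cldn4, Krt7 and Htr3a are higher in all 5.

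Gene groups were compared through 31 lists. With camera's preset correlation, 11 lists were higher and 6 lower in cKO. With an estimated correlation camera called 0 lists, with 4 at an unadjusted p under 0.05, and fry called 4 (nuclear respiratory chain, ion and water transport, epithelial injury, steroid receptors). The mean expression of each list was compared by an exact permutation test (two-sided p, not adjusted). It differed at p under 0.05 for ion and water transport, the nuclear respiratory chain and junctions (0.00794 each), epithelial injury (0.0159) and epididymal markers (0.0317). It also differed for interferon and mitochondrially encoded transcripts (0.0397 each) and early response genes (0.0476), and p was 0.738 for motile cilia. In the junction list Cldn4 alone had a log2 fold change of 2.84, while the list's median was -0.01. The camera p-values given for lists are Benjamini-Hochberg adjusted over the 31 lists. Members are counted from edgeR adjusted over all genes tested and, beside it, adjusted over the list alone. List calls under other settings all used the preset correlation of 0.01. The estimated correlation was above this for every list but steroid receptors (-0.02), such as 0.40 for primary cilium, 0.61 for motile cilia, 0.66 for endothelium and 0.85 for germ cells. Such calls can therefore overstate the evidence where members vary together between libraries.

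Genes of the absorptive cell take up most of the fluid that leaves the testis. Of 45 measured genes of ion and water transport 5 fell, and adjusted over the list alone 14 fell and 1 rose. The median log2 fold change was -0.21 (camera adjusted p = 2.76e-04, adjusted p = 0.365 with an estimated correlation). On unscaled TPM this median was 0.05, which is -0.15 relative to the median of all genes. The members that fell were Aqp1 (chromosome 6, 55336432 to 55348555, plus strand), at -0.64 ± 0.14 (SE), the water channel Aqp2 at -1.50 ± 0.25, the sodium pump subunits Atp1b1 and Fxyd2 at -0.37 ± 0.08 and -1.18 ± 0.25, and the potassium channel Kcnj16 at -0.29 ± 0.06 (0.0013 on unscaled TPM), with adjusted p between 0.0217 and 0.0467 (edgeR, Benjamini-Hochberg). With each library left out in turn, Aqp2 was called in 5 of 10 fits, Aqp1, Fxyd2 and Kcnj16 in 2 and Atp1b1 in 1, all with the same sign. Slc9a3, the apical sodium-proton exchanger of fluid reabsorption, had a log2 fold change of -0.61 ± 0.14 and an adjusted p of 0.058 (edgeR, Benjamini-Hochberg). Values for Cftr, the apical chloride channel, the solute channel Aqp9 and the carbonic anhydrase Car2 were -0.23 ± 0.06, -0.45 ± 0.22 and -0.04 ± 0.14, none past the threshold.

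Of 29 measured brush border and apical scaffold genes 7 fell and 1 rose, and adjusted over the list alone 12 fell and 2 rose. The median was -0.16 (camera adjusted p = 0.00212, adjusted p = 0.599 with an estimated correlation), and on unscaled TPM it was 0.06, or -0.14 relative to all genes. Besides Vil1, the microvillar cadherin Cdhr5 fell by 0.87 ± 0.14 on the log2 scale, its partner Anks4b by 0.59 ± 0.08 and the scaffold Pdzk1 by 0.61 ± 0.10 (edgeR, Benjamini-Hochberg adjusted p = 0.0195, 0.014 and 0.0228). Muc1, a membrane mucin named here after its value was seen, was the member that rose (log2 fold change 1.22). With the macrophage score as a covariate the brush border median was -0.06 and the call was lost (camera adjusted p = 0.125). In the 6 animals numbered below 2900 it was also -0.06 (camera adjusted p = 0.176) and that of ion and water transport -0.17 (camera adjusted p = 0.0118).

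Of 36 measured genes of endocytosis and lysosome, 1 fell, and 3 adjusted over the list alone, with a median of -0.03 (camera adjusted p = 0.368) that was 0.05 with library totals alone (-0.04 relative to all genes) and 0.22 on unscaled TPM (0.02 relative). The member that fell was Amn, the partner of cubilin, at -1.23 ± 0.19. Lrp2, the large endocytic receptor megalin, was at 1154 ± 157 against 1849 ± 438 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.0688) and Cubn at 5.53 ± 2.65 against 6.27 ± 1.55 (adjusted p = 0.797). Among 20 measured genes of steroid receptors and oestrogen response, 1 fell, and 1 adjusted over the list alone. Their median was -0.10 (camera adjusted p = 0.0565; fry adjusted p = 0.0206) and 0.14 on unscaled TPM, or -0.06 relative to all genes. The list was called without cKO 4 (camera adjusted p = 0.0453) and in limma voom (camera adjusted p = 0.0352). The member was Srd5a2 (chromosome 17, 74016955 to 74047916, minus strand), at -1.20 ± 0.14 (edgeR, Benjamini-Hochberg adjusted p = 0.00907). Esr1, the oestrogen receptor on which fluid reabsorption in these ductules depends, was at 720 ± 47.5 against 770 ± 88.5 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.568). Of 29 measured genes of tight and adherens junctions 2 rose and 0 fell, and adjusted over the list alone 2 rose and 3 fell. Their median was -0.01 and their mean 0.13, and camera's direction was up (adjusted p = 0.673). Their mean expression was 0.13 higher, with every cKO library above every control (exact permutation test, two-sided, p = 0.00794). The closest libraries were control 5 at 5.834 and cKO 3 at 5.857 log2 CPM. Cldn4, with a log2 fold change of 2.84, weighs heavily in a mean of 29 genes, and the score without it was not computed. The median was 0.0011 with DESeq2 size factors, 0.01 with upper quartiles, 0.08 with library totals alone and 0.21 on unscaled TPM, the last 2 -0.01 and 0.0025 relative to all genes. In the animals numbered below 2900 it was 0.08 and the list was called (camera adjusted p = 0.0378). The members that rose were Cldn4 and Cldn3, the latter by 0.62 ± 0.09 on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 0.0187).

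Of 43 measured nuclear genes of the respiratory chain 15 fell and 0 rose, adjusted over the list alone 35 fell, and the median log2 fold change was -0.24 (camera adjusted p = 2.77e-19, adjusted p = 0.365 with an estimated correlation). Ndufa4, a subunit associated with cytochrome c oxidase, fell by 0.34 ± 0.05 on the log2 scale (SE). Ndufs8 and Ndufs1, iron-sulphur subunits of complex I, fell by 0.45 ± 0.08 and 0.24 ± 0.04 on the log2 scale, the latter at 0.03 on unscaled TPM. Sdhc, a subunit of succinate dehydrogenase, fell by 0.28 ± 0.05 and was at 0.15 on unscaled TPM. These 4 genes had adjusted p between 0.0181 and 0.029 (edgeR, Benjamini-Hochberg). The mean expression of the list fell by 0.23 on the log2 scale, with every cKO library below every control (exact permutation test, two-sided, p = 0.00794, the smallest that 5 against 5 allows). All 13 mitochondrially encoded transcripts had lower estimates. Of them 1 fell, and 8 adjusted over the list alone, with a median of -0.31 (camera adjusted p = 4.46e-06, adjusted p = 0.599 with an estimated correlation). The member was mt-Nd6, at -0.42 ± 0.08, whose end overlaps that of mt-Nd5 on the opposite strand; whether reads of the pair were shared was not tested. Control 5 lay apart for the mitochondrially encoded transcripts, at a mean of 9.51 against 9.90 to 9.97 log2 CPM in the other controls. Of 39 measured genes of glutathione and oxidative stress 1 fell, and adjusted over the list alone 6 fell and 2 rose. The median was -0.08 (camera adjusted p = 0.00472, adjusted p = 0.599 with an estimated correlation) and turned positive with library totals alone (0.01) and unscaled TPM (0.10), -0.08 and -0.10 relative to all genes. On unscaled TPM the call was lost (camera adjusted p = 0.0781). The member was the superoxide dismutase Sod1, which fell by 0.35 ± 0.07 on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 0.0414).

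Few ciliary transcripts passed the threshold, as was true of all genes tested (104 higher and 283 lower of 17552). Of 78 measured genes of motile cilia and the multiciliated cell programme 2 fell, and 3 adjusted over the list alone, with a median of -0.14 (camera adjusted p = 0.0163, adjusted p = 0.895 with an estimated correlation). At an unadjusted p under 0.05 in edgeR 5 were higher and 19 lower. DESeq2 called 1 higher and 4 lower, and limma voom 1 lower. On unscaled TPM the median was 0.07, -0.13 relative to all genes. Cfap126, a basal body protein, fell by 0.73 ± 0.14 on the log2 scale and the cilium tip protein Sntn by 0.59 ± 0.13 (edgeR, Benjamini-Hochberg adjusted p = 0.0312 and 0.0478). Foxj1, the master regulator of motile cilia, was at 478 ± 54.5 against 639 ± 123 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.144). The list's call was lost without control 2, control 3, control 5, cKO 1 or cKO 3 (highest camera adjusted p = 0.144), and its median was 0.04 in the animals numbered below 2900. It was -0.24 without control 1 (camera adjusted p = 1.79e-08) and -0.30 with the germ cell covariate (camera adjusted p = 2.67e-09). With the number series as a covariate the call was lost (median -0.05, camera adjusted p = 0.752), and with the macrophage covariate the list was called higher (median 0.14, camera adjusted p = 7.5e-06). No member of the list of 81 primary cilium and intraflagellar transport genes passed in edgeR, over all genes or adjusted over the list alone, with 1 higher and 6 lower at an unadjusted p under 0.05, 4 lower in DESeq2 and 0 in limma voom. Its median was -0.04 (camera adjusted p = 0.233), 0.05 with library totals alone (-0.04 relative to all genes) and 0.20 on unscaled TPM (-0.0039 relative). The list was called lower without control 1 (median -0.11, camera adjusted p = 1.06e-04), with voom sample weights (median -0.11) and with the germ cell covariate (median -0.09, camera adjusted p = 0.00142). It was called higher in the animals numbered below 2900 (median 0.07, camera adjusted p = 0.0334) and with the macrophage covariate (median 0.11, camera adjusted p = 2.25e-05). Pkhd1 and Pkd1, both genes of polycystic kidney disease, had log2 fold changes of 0.02 ± 0.12 and 0.03 ± 0.08. Of 25 hedgehog pathway genes 1 fell, also adjusted over the list alone, with a median of -0.02 (camera adjusted p = 0.865) that was 0.06 with library totals and 0.15 on unscaled TPM, or -0.03 and -0.06 relative to all genes. This was the cyclin Ccnd1, at 218 ± 41.7 against 350 ± 43.4 CPM, which many other pathways also regulate. The hedgehog targets Gli1 and Ptch1, at -0.21 ± 0.23 and -0.18 ± 0.19, were not past the threshold. Of 21 enzymes of tubulin glutamylation and glycylation 0 passed in edgeR, over all genes or adjusted over the list alone, with 1 higher and 2 lower at an unadjusted p under 0.05 and 0 in DESeq2 and limma voom (median 0.31, camera adjusted p = 0.0998). The tubulin list was called higher without control 2, cKO 1 or cKO 3 (medians 0.37, 0.38 and 0.44; camera adjusted p = 0.0404, 0.0435 and 0.0202), with the number series as a covariate (0.39; camera adjusted p = 0.00415), with the macrophage covariate (0.63), with 1 surrogate variable and on TPM with a pseudocount of 1. Its median was 0.10 without cKO 5, and it was called lower with the germ cell covariate (-0.11; camera adjusted p = 0.0497). Agbl5, a deglutamylase, was at 0.57 ± 0.29 and Ttll4, a glutamylase, at 0.08 ± 0.08. Of 44 genes of Wnt and planar cell polarity 0 passed in edgeR, also adjusted over the list alone, with 6 higher and 7 lower at an unadjusted p under 0.05, 1 higher and 3 lower in DESeq2 and 0 in limma voom. Their median was 0.003 and camera's direction was down (adjusted p = 0.953). The co-receptor Lrp5 was at -0.40 ± 0.11 and the planar polarity cadherin Celsr1 at -0.37 ± 0.15.

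**Figure D2:**
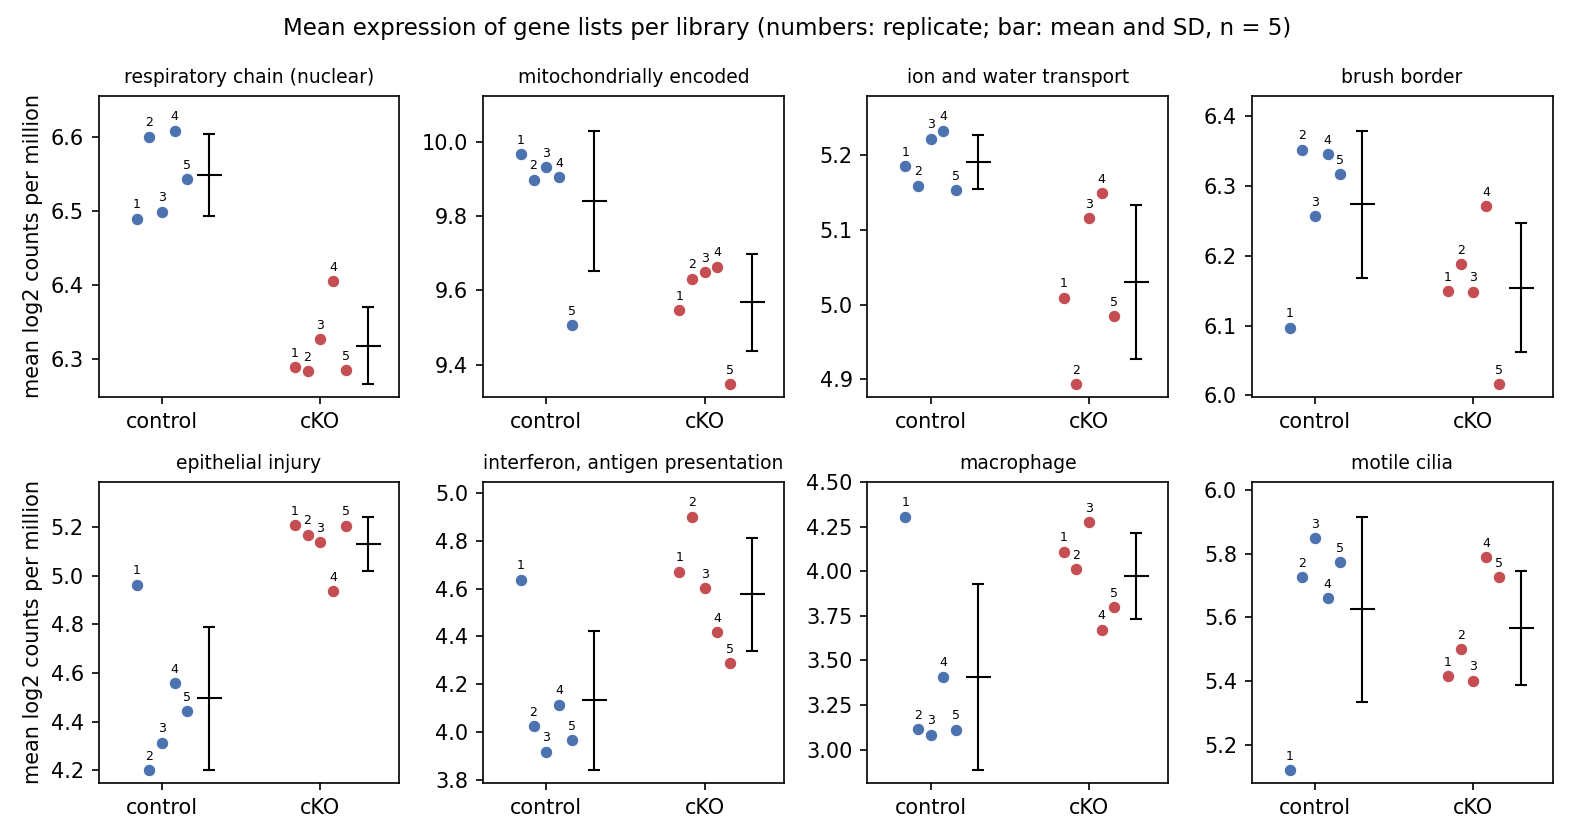
Mean expression in log2 CPM (vertical axes) of 8 gene lists in each control (blue) and cKO (red) library, with replicate numbers and the mean and SD of 5 libraries. All cKO libraries lie below all controls for nuclear respiratory chain and transport genes, whose medians turn positive on unscaled TPM while staying below the median of all genes, and control 1 lies apart from the other controls for interferon, macrophage and motile cilia genes.

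The list of injured and remodelling epithelium was called higher with the preset correlation. Of 36 measured members 3 rose and 1 fell, and adjusted over the list alone 11 rose and 2 fell, with a median of 0.49 (camera adjusted p = 9.51e-06, adjusted p = 0.374 with an estimated correlation; fry adjusted p = 0.0161). With the macrophage score as a covariate the median was 0.09 (camera adjusted p = 0.0281), and control 1, rich in macrophage transcripts, had a list score of 4.96, within the range of the cKO libraries (4.94 to 5.21). Besides Cldn4, Krt7 (chromosome 15, 101411043 to 101430313, plus strand) rose by 1.72 ± 0.25 on the log2 scale and the annexin Anxa3 by 0.74 ± 0.13, and the surface glycoprotein Cd24a fell by 0.37 ± 0.08 (edgeR, Benjamini-Hochberg adjusted p = 0.0187, 0.0268 and 0.0467). The secreted chaperone Clu, at 336 ± 77.2 against 214 ± 36.9 CPM, and the siderophore-binding Lcn2, at 1017 ± 286 against 624 ± 76.8, were higher in all 5 cKO libraries than in any control without passing (edgeR, Benjamini-Hochberg adjusted p = 0.0752 and 0.0683). Of 29 measured early response genes 1 rose and 1 fell, and adjusted over the list alone 2 rose and 2 fell, with a median of 0.25 (camera adjusted p = 9.02e-04, adjusted p = 0.606 with an estimated correlation). This median was 0.51 without control 1 and 0.15 without control 2, and with the macrophage covariate it was 0.03 and the call was lost (camera adjusted p = 0.773). Nr4a1, an immediate early nuclear receptor, rose by 1.16 ± 0.14 on the log2 scale and the heat shock protein Hsph1 fell by 0.49 ± 0.11 (edgeR, Benjamini-Hochberg adjusted p = 0.00907 and 0.047). Of 36 measured cell cycle genes 0 passed over all genes in edgeR, 20 had an unadjusted p under 0.05 (16 higher, 4 lower), 13 passed in DESeq2 (10 higher, 3 lower) and 0 in limma voom. Adjusted over the list alone 12 were higher, among them the mitotic genes Ccnb1, Cenpf and Foxm1, and 3 lower, the replication helicase genes Mcm2, Mcm4 and Mcm5. The median was 0.56 (camera adjusted p = 0.00504, adjusted p = 0.682 with an estimated correlation). With the germ cell score as a covariate it was 0.35 (camera adjusted p = 0.141), with the macrophage score 0.51 (camera adjusted p = 0.0747), and in the animals numbered below 2900 0.33 (camera adjusted p = 0.26), so that the call was lost in each. Leaving out control 5 and cKO 5 together also ended it (median 0.42, camera adjusted p = 0.0564).

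Of the 7 immune lists, 5 were called higher with the preset correlation, and none with an estimated correlation or by fry. Of 40 measured interferon response and antigen presentation genes 2 rose, and 4 adjusted over the list alone, with 37 estimates above 0 and a median of 0.37 (camera adjusted p = 2.7e-07, adjusted p = 0.599 with an estimated correlation). Bst2, which tethers budding virions, rose by 0.50 ± 0.10 on the log2 scale and the class II antigen H2-Eb1 by 0.89 ± 0.20 (edgeR, Benjamini-Hochberg adjusted p = 0.0404 and 0.0478). With the number series as a covariate the median was 0.25 (camera adjusted p = 5.13e-04), and in the animals below 2900 it was 0.26 (camera adjusted p = 3.99e-05). Of 32 measured macrophage and dendritic cell markers 1 rose, the Gpnmb described above, also adjusted over the list alone, with a median of 0.23 (camera adjusted p = 5.3e-04, adjusted p = 0.682 with an estimated correlation). This median was 0.61 without control 1, 0.35 without cKO 4, and between 0.20 and 0.29 without any of the other libraries. Summed over the list, macrophage transcripts were at 1277, 596, 577, 647 and 491 CPM in control libraries 1 to 5 and at 1153, 1080, 1303, 815 and 895 in cKO libraries 1 to 5 (exact permutation test, two-sided, p = 0.0794). The macrophage sums were taken from library totals, without the scaling factors. With the macrophage score as a covariate the interferon median was 0.16 (camera adjusted p = 0.184).

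Of 25 measured complement and acute phase genes 1 rose, and 2 adjusted over the list alone, with a median of 0.18 (camera adjusted p = 0.0163, adjusted p = 0.682 with an estimated correlation). The member was Pglyrp1, a peptidoglycan recognition protein, at 1.56 ± 0.27 (edgeR, Benjamini-Hochberg adjusted p = 0.0268). No member of the list of 30 cytokines and chemokines passed in edgeR, with 4 higher and 1 lower at an unadjusted p under 0.05, 3 higher in DESeq2 and 0 in limma voom. Adjusted over the list alone 2 were higher, and the median was 0.15 (camera adjusted p = 0.0219, adjusted p = 0.722 with an estimated correlation). Ccl28, a mucosal chemokine, was at 190 ± 46.7 against 142 ± 32.6 CPM. Of 20 measured T and NK cell markers 1 rose, Trbc2, whose reads a near-identical gene can share, also adjusted over the list alone. The list's median was 0.20 (camera adjusted p = 0.0219, adjusted p = 0.682 with an estimated correlation). The calls of these 3 lists were lost without single libraries: the complement list without control 3, control 5, cKO 1 or cKO 2 (highest camera adjusted p = 0.0737), the cytokine list without control 2, control 5, cKO 1 or cKO 2 (0.121), and the T and NK cell list without control 2, control 5 or cKO 2 (0.121). Without control 1 their medians were 0.40, 0.53 and 0.42. With the macrophage covariate all 3 calls were lost, at medians of -0.10, -0.22 and 0.05 (camera adjusted p = 0.317, 0.176 and 0.868), and with the number series as a covariate those of the complement and cytokine lists (camera adjusted p = 0.258 and 0.186). Library totals alone also ended all 3 (camera adjusted p = 0.0658, 0.104 and 0.0965), unscaled TPM the cytokine and T and NK cell calls (0.157 and 0.436), and a filter of 1 CPM the latter (0.231). In the animals below 2900 none of the 3 was called, nor were macrophage markers, at a median of 0.03 (camera adjusted p = 0.0625). Of 22 B and plasma cell markers 0 passed in edgeR, also adjusted over the list alone, with 1 higher and 3 lower at an unadjusted p under 0.05 and 0 in DESeq2 and limma voom (median 0.06, camera adjusted p = 0.632). Of 13 neutrophil, eosinophil and mast cell markers 0 passed in edgeR, also adjusted over the list alone, with 1 lower at an unadjusted p under 0.05 and 0 in DESeq2 and limma voom. The median of this list was -0.11, while camera's direction was up (adjusted p = 0.84), and 0.05 on unscaled TPM without a filter.

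Markers of neighbouring tissues differed widely between libraries. Summed germ cell transcripts were at 170, 1734, 590, 215 and 206 CPM in control libraries 1 to 5 and at 1209, 475, 531, 2214 and 3535 in cKO libraries 1 to 5 (exact permutation test, two-sided, p = 0.167). Of 39 measured germ cell transcripts 0 passed in edgeR, also adjusted over the list alone, with 8 higher at an unadjusted p under 0.05, 2 higher in DESeq2 and 0 in limma voom. The list's median was 1.79 (camera adjusted p = 6.45e-11, adjusted p = 0.606 with an estimated correlation), 3.37 without control 2, 1.13 without cKO 5 and 0.37 in the animals numbered below 2900. Prm2, a protamine of condensing spermatids, was at 167 ± 133 against 49.4 ± 81.8 CPM. The first principal component held 60.6% of the variance of log2 CPM, its leading genes were germ cell genes such as Akap3, and it did not separate the genotypes (exact permutation test, two-sided, p = 0.0635). Epididymal transcripts summed to 434, 204, 168, 200 and 167 CPM in controls 1 to 5 and to 227, 699, 364, 407 and 7468 in cKO 1 to 5 (exact permutation test, two-sided, p = 0.0714). Of 16 measured epididymal markers 1 rose and 1 fell, and adjusted over the list alone 10 rose and 1 fell, with a median of 3.60 (camera adjusted p = 0.00987, adjusted p = 0.682 with an estimated correlation). Without cKO 5 the median was 0.67 and the list was no longer called (camera adjusted p = 0.0966). The call was also lost with a filter of 1 CPM (median 1.00, camera adjusted p = 0.163), voom sample weights (median 1.03, camera adjusted p = 0.0905), the germ cell covariate (median 1.37, camera adjusted p = 0.157), library totals alone (camera adjusted p = 0.0965) and in the animals numbered below 2900 (median 0.35, camera adjusted p = 0.194). The member that rose was Adam7, an epididymal membrane protease, at 291 ± 352 against 5.89 ± 5.57 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.0467), and the one that fell was the uncertain Klk1b21. Of 18 Sertoli and Leydig cell transcripts 0 passed in edgeR, also adjusted over the list alone, with 5 higher and 1 lower at an unadjusted p under 0.05, 1 higher in DESeq2 and 0 in limma voom. The median was 0.59 (camera adjusted p = 0.0196, adjusted p = 0.659 with an estimated correlation), and the call was lost without control 1, control 2 or cKO 2 (highest camera adjusted p = 0.262), with library totals alone (camera adjusted p = 0.0658), with voom sample weights (0.0904) and with the macrophage covariate (0.0726).

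**Figure D3:**
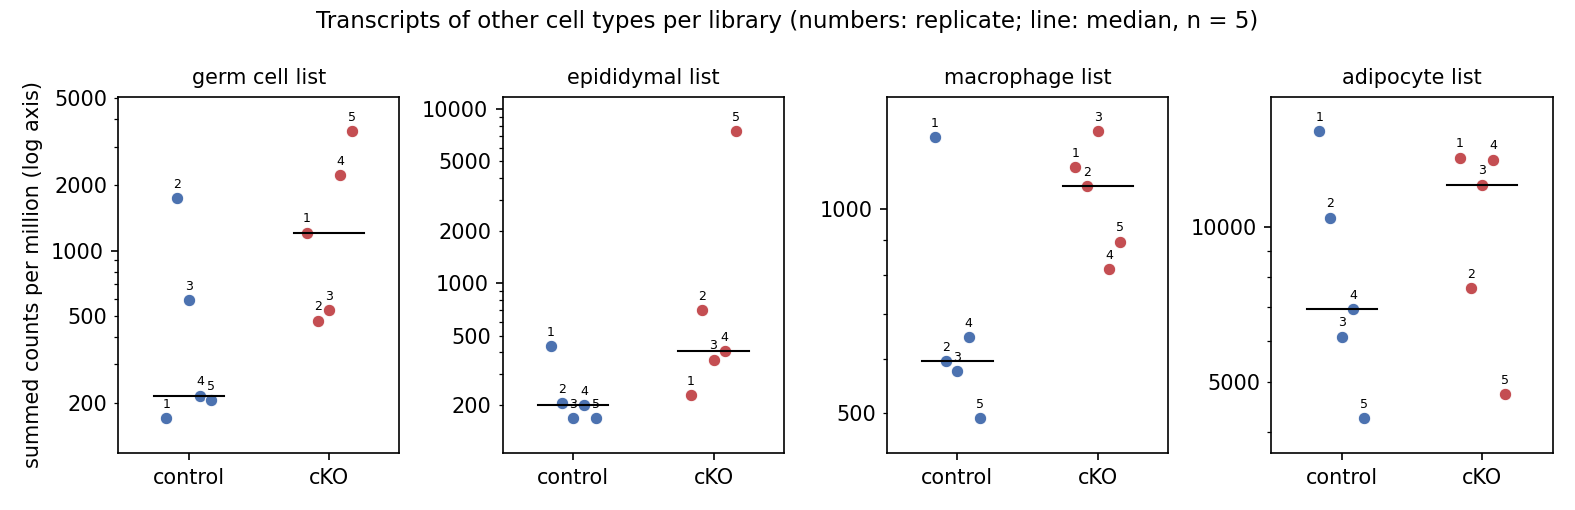
Summed CPM on log axes of the germ cell, epididymal, macrophage and adipocyte lists in each control (blue) and cKO (red) library, with replicate numbers and the median of 5 libraries as a line. Sums were taken from library totals, without the scaling factors. cKO 5 holds the most germ cell and epididymal transcripts (3535 and 7468), and control 1 holds more macrophage transcripts (1277) than the other controls.

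In the comparison of all libraries no list of stromal or blood markers was called. Of 43 extracellular matrix and fibroblast markers 0 passed in edgeR, also adjusted over the list alone, with 2 higher and 1 lower at an unadjusted p under 0.05 and 0 in DESeq2 and limma voom (median 0.04, camera adjusted p = 0.259). Without control 1 the list was called higher (median 0.24, camera adjusted p = 9.54e-04), and with the macrophage covariate lower (median -0.20, camera adjusted p = 0.00202). Col1a1 and Col3a1, the main fibrillar collagens, were at -0.04 ± 0.21 and 0.11 ± 0.33. Of 25 smooth muscle markers 3 fell, also adjusted over the list alone, with a median of -0.09 (camera adjusted p = 0.185), and 0.15 on unscaled TPM, or -0.06 relative to all genes. Without cKO 5 the median was -0.28 and the list was called (camera adjusted p = 0.0125), while without control 5 or cKO 4 it was 0.09 or 0.02. The smooth muscle list was also called lower in the animals numbered below 2900 (median -0.20, camera adjusted p = 0.0334). The same held without control 1 and cKO 5 (-0.30, camera adjusted p = 0.0104) and with no filter (-0.10, camera adjusted p = 0.0433). The members that fell were the creatine kinase Ckb, the myosin light chain kinase Mylk and the calmodulin-binding Pcp4, at -0.71 ± 0.13, -0.52 ± 0.10 and -1.48 ± 0.33 (edgeR, Benjamini-Hochberg adjusted p = 0.029, 0.0312 and 0.0497). Of 28 endothelial markers 0 passed in edgeR, also adjusted over the list alone, with 2 higher at an unadjusted p under 0.05, 1 higher in DESeq2 and 0 in limma voom (median -0.10, camera adjusted p = 0.978; 0.17 on unscaled TPM, -0.03 relative to all genes, and 0.20 without control 1). With the macrophage covariate the endothelial list was called lower (median -0.51, camera adjusted p = 3.3e-06). The vascular receptor Kdr was at 0.31 ± 0.13. Of 25 adipocyte markers 0 passed in edgeR, also adjusted over the list alone, with 1 higher at an unadjusted p under 0.05 and 0 in DESeq2 and limma voom (median 0.13, camera adjusted p = 0.14). The adipocyte list was called higher without control 1 (median 0.63, camera adjusted p = 0.008) or cKO 5 (median 0.31, camera adjusted p = 0.00349), and its median was -0.01 without control 5. Adipocyte transcripts summed to between 4252 and 15379 CPM (exact permutation test, two-sided, p = 0.524). Of 6 measured blood transcripts 0 passed in edgeR, also adjusted over the list alone, with 1 lower at an unadjusted p under 0.05 and 0 in DESeq2 and limma voom. The blood median was 0.005, and camera's direction was down (adjusted p = 0.959).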

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

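The tests of the germ cell and interferon patterns in this part were chosen only after those results were seen. In 152 groups of 5 libraries, the gap between the highest or lowest library and the nearest other was divided by the range of the group. Of these ratios 18 exceeded 0.71, where chance would give about 7.6 if values were normally distributed. Sums and percentages were not put on a log scale, and the groups share libraries, so 7.6 is a rough guide only.

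Control 1 lay apart in 9 of these groups. It held more epididymal transcripts than the other controls (434 against 167 to 204 CPM, ratio 0.863). In the controls the most abundant gene of that list was Mfge8 (184 ± 93.5 CPM, SD), against 235 ± 113 CPM for the whole list. The sum therefore rests largely on 1 gene, and the epididymal score of control 1 (1.18 against 0.26 to 0.59) was not flagged. Control 1 also held more macrophage transcripts (1277 against 491 to 647 CPM, ratio 0.801). Its mean log2 CPM was higher for macrophage markers (4.31 against 3.08 to 3.41, ratio 0.734), interferon and antigen presentation genes (4.64 against 3.92 to 4.11, ratio 0.728), extracellular matrix genes (7.47 against 6.54 to 6.76, ratio 0.761) and endothelial markers (5.84 against 4.90 to 5.16, ratio 0.724). It was lower for motile cilia (5.12 against 5.66 to 5.85, ratio 0.742) and primary cilium genes (4.96 against 5.29 to 5.34, ratio 0.861). The macrophage glycoprotein Gpnmb was also highest there (25.9 against 1.94 to 5.27 CPM, ratio 0.861).

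Control 5, the library with the lowest total, had the largest share of Lars2, a mitochondrial leucyl-tRNA synthetase gene, among its counts (6.78% against 0.00714 to 1.05%, ratio 0.846). It also had the largest share of pseudogenes (11.98% against 6.87 to 10.82% in the other controls) and the lowest scaling factor (0.8602). The source of the reads counted for Lars2 was not tested, so this share may reflect the library and not expression of the gene. The scores of control 5 were lowest among controls for steroid receptor genes (5.10 against 5.36 to 5.43, ratio 0.785) and mitochondrially encoded transcripts (9.51 against 9.90 to 9.97, ratio 0.852). Control 2 held more germ cell transcripts than the other controls (1734 against 170 to 590 CPM, ratio 0.731). Among cKO libraries, cKO 5 held the most epididymal transcripts (7468 against 227 to 699 CPM, ratio 0.935), as did its epididymal score (6.32 against 0.62 to 2.02, ratio 0.754), and the least of the transporter Slc16a14 (3.92 against 5.73 to 6.13 CPM, ratio 0.819). In cKO 4 the epithelial injury score was lower than in the other cKO libraries (4.94 against 5.14 to 5.21, ratio 0.743), and in cKO 2 the kallikrein Klk1b21 was higher (0.768 against 0.483 to 0.538 CPM, ratio 0.807).

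Germ cell transcripts ranged from 170 to 1734 CPM in controls and from 475 to 3535 CPM in cKO libraries. Their score was 2.77 higher in cKO on the log2 scale, with an exact permutation p of 0.0714, so that genotype and uneven sampling cannot be told apart with 5 libraries per group. Leydig cell genes, which testis tissue carried into the sample would bring along, did not rise with them (Pearson r = -0.137, permutation p = 0.748; Spearman rho = -0.333, permutation p = 0.349; 1 relation computed). Without the 2 libraries farthest from the median r was -0.313, and with 5 Leydig genes, all of which are also in the Sertoli and Leydig list and 2 of which reach 1 CPM in every control, the test leaves carried-over tissue open. The most abundant genes were Odf2 (235 ± 148 against 118 ± 59.3 CPM, SD), Prm2 (167 ± 133 against 49.4 ± 81.8) and Spata18 (103 ± 18.1 against 105 ± 21.4) for germ cells, of which 7 of 39 reach 1 CPM in every control, and Insl3 (11 ± 21.5 against 3.93 ± 4.25), Star (9.23 ± 1.60 against 7.78 ± 1.26) and Cyp11a1 (5.40 ± 5.98 against 1.58 ± 0.766) for Leydig cells. Single cKO libraries at 49.4 and 15.9 CPM raised the means of Insl3 and Cyp11a1. Sperm in the lumen, which a difference in fluid transport between genotypes could alter, was not tested.

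Interferon and antigen presentation genes had a score 0.444 higher in cKO on the log2 scale (exact permutation p = 0.0397). Within the series of animal numbers the difference was 0.306 (0.317 below 2900 and 0.288 above; exact permutation within series, 60 assignments, p = 0.0833). Most of the difference was kept within series, but this p leaves the series open, and it cannot be told apart from genotype. The macrophage score was 0.568 higher (exact permutation p = 0.0635), and the interferon score minus the macrophage score differed by -0.124 (exact permutation p = 0.421), so a larger share of macrophages may account for the pattern and cannot be told apart from a response within other cells. Of the 32 macrophage markers 31 reach 1 CPM in every control and 3 are in other lists. The most abundant were Lyz2 (168 against 112 CPM), Csf1r (111 against 104) and Mrc1 (85.7 against 85.8).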

How the results depend on the processing

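Settings with pairs of libraries left out, germ cell or macrophage scores as covariates, pseudogenes or repeated features left out and scaled TPM were chosen only after the data were seen. Over all settings, comparisons of named genes stayed on their side of the threshold in 3503 cases, lost the call in 957, gained it in 137 and reversed in 10, and lists did so in 960, 70, 38 and 14. Among the 3503 and 960 cases, 107 and 68 changed sign while past the threshold in neither setting. The number of called genes (387; 104 higher, 283 lower) stayed within 1.5 times under DESeq2 size factors (305), upper quartiles (279), a filter of 1 CPM (395), limma voom (296), robust empirical Bayes (372), unrounded counts (386), and without epididymal, germ cell and blood genes (381), pseudogenes (385) or repeated features (385).

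Under the other settings it moved, and unless stated the cause was not tested. It was 125 (70 higher, 55 lower, 6 lists higher) with library totals alone, 185 (47, 138) with no filter, 1526 (653, 873) with DESeq2, 1862 (667, 1195) with voom sample weights, 25 (24, 1) on TPM with a pseudocount of 1, 23 (22, 1) with 0.1, and 3 (3 higher, 0 lower) without a filter. Unscaled TPM moved the median of all genes to 0.20, 0.23 and 0.11, and with trimmed-mean scaling 189 (45, 144) were called. The animal-number series as covariate gave 165 (69, 96), the animals below 2900 gave 0 (0 higher, 0 lower) in edgeR, with 1203 at an unadjusted p under 0.05, 162 by DESeq2 and 0 by voom, and 1 surrogate variable gave 755 (257, 498). All 387 main calls kept their sign in the animals below 2900. A fold above 1.5 left 6 (5, 1) and an adjusted p under 0.01 left 14 (6, 8), by construction. Without control 5 and cKO 5 there were 27 (8, 19), without control 1 and cKO 5 1827 (774, 1053), with the germ cell covariate 21 (8, 13), and with the macrophage covariate 731 (533, 198; 6 lists higher). Of these calls, 387 of the main ones were among the 1526 of DESeq2, 119 among the 125 of library totals and 147 among the 731 of the macrophage covariate.

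The labels do not say that the replicate numbers pair the mice. Same-numbered libraries had correlations of deviations from -0.649 to 0.129, 1 of 5 above 0.1, and 1 of 5 cKO libraries correlated best with its own number. These correlations cover all tested genes, whose first principal component (60.6% of the variance) was led by germ cell genes. They therefore cannot exclude a shared litter, day or batch. With the replicate number as a block 4 genes were called (2 higher, 2 lower).

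Leaving out 1 library gave between 22 (without control 4) and 1869 genes (without control 1), with 9 to 685 higher, 13 to 1184 lower, and 7 (without cKO 2) to 12 lists higher. The counts were 30, 41 and 38 without controls 2, 3 and 5, and 104, 39, 115, 199 and 153 without cKO 1 to 5. Of the 387 called genes, 386 were tested in all 10 fits, and all 386 kept their sign and an unadjusted p under 0.05 (edgeR). The log2 fold changes of the 56 called named genes moved by no more than 1.5 times in any of these fits. Cldn4, Htr3a, Lad1, Nr4a1, Snap91 and Srd5a2 were called in all 10. All 56 stayed called without control 1, but only between 7 (without control 2 or 4) and 33 (without cKO 4) did in the other fits. Among absorptive genes, Anks4b was called in 9 fits, Aqp2 and Cdhr5 in 5, Vil1 in 4 and Pdzk1 in 3. Aqp1, Fxyd2 and Kcnj16 were called in 2 and Atp1b1 in 1.

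On TPM with pseudocounts of 1, 0.1 and 1 without a filter, Kcnj16 turned to 0.00132, 0.00118 and 0.00132, Sdhc to 0.150, 0.152 and 0.150, and Ndufs1 to 0.0329, 0.0343 and 0.0329, with the shift of all genes. In the animals below 2900 the medians turned to 0.0387 for motile cilia and 0.0745 for primary cilium, and camera's direction for Wnt genes, but not their median (0.0126), turned up. The endothelial median was 0.228 with voom sample weights, 0.287 without control 1 and cKO 5, where Ighm was at 0.967, and 0.25 with the germ cell covariate, but -0.512 with the macrophage covariate. The germ cell covariate turned tubulin modification to -0.105 and the germ cell list, which it is made from, to -0.0124. The macrophage covariate turned motile cilia to 0.141, primary cilium to 0.112, cytokines to -0.217, complement to -0.0961, extracellular matrix to -0.204 and the macrophage list, which it is made from, to -0.176.

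Lists gained calls as well. Adipocyte markers were called with the replicate block (0.374), 1 surrogate variable (0.318), voom sample weights (0.681) and both pairs of libraries left out, and extracellular matrix markers with sample weights (0.236), without control 1 and cKO 5 (0.229) and with the germ cell covariate (0.293). B and plasma cell markers were called with that covariate (0.605). T and NK cell markers lost their call without a filter (0.124), and motile cilia on TPM without a filter (0.0737).

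In counts simulated at these depths and spreads edgeR recovered 29.9% of 1.5-fold and 92.3% of 4-fold changes, so that smaller changes were often missed. The simulation changed no gene of low count and drew genes independently. Its rates therefore do not cover low-count genes or variation that genes share between libraries.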

Other observations

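The peroxisome, fatty acid oxidation and citric acid cycle lists, and the genes named in the next paragraph, were chosen only after the called genes were seen, while the tests of the respiratory and absorptive patterns and of other splits were written before their results.

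Some transcripts of oxidative metabolism outside the respiratory chain also fell in cKO ductules. Of 52 tested peroxisome genes, 2 of which are also in the other lists, 8 fell where 0.838 would be called lower by chance (Fisher's exact test p = 1.68e-06), 40 had lower estimates and 12 fell adjusted over the list alone. Their median log2 fold change was -0.15 (fry, Benjamini-Hochberg adjusted p = 0.00485; camera with an estimated correlation, adjusted p = 0.0775). Of 19 genes of mitochondrial fatty acid oxidation 3 fell (Fisher's exact test p = 0.00332), all 19 had lower estimates, 6 fell adjusted over the list alone, and the median was -0.18 (camera with an estimated correlation, adjusted p = 0.0951). Of 18 genes of the citric acid cycle 2 fell (Fisher's exact test p = 0.0334), 15 had lower estimates, 10 fell adjusted over the list alone, and the median was -0.19 (camera with an estimated correlation, adjusted p = 0.0775). On unscaled TPM the 3 medians were 0.08, 0.08 and 0.07, which is -0.12, -0.12 and -0.13 relative to all genes. Since these lists were written after the called genes had been read, their p-values describe the pattern and do not test it. Among transcription factors of absorptive epithelia and of oxidative metabolism, Hnf4a fell by 0.71 ± 0.11 on the log2 scale (SE), Hnf1a by 0.68 ± 0.11, Ppara by 0.65 ± 0.13 and the coactivator Ppargc1a by 0.37 ± 0.08 (edgeR, Benjamini-Hochberg adjusted p = 0.019, 0.019, 0.0378 and 0.0449). The peroxisomal oxidase Acox1 was at 477 ± 64.0 against 662 ± 32.1 CPM, the urate oxidase Uox at 18.3 ± 3.25 against 34.7 ± 6.35, the kynurenine hydroxylase Kmo at 12 ± 1.61 against 26.4 ± 2.62 and the brush border maltase Mgam at 62.7 ± 13.2 against 124 ± 14.6. Among genes that rose were the integrin Itga2 (14.0 ± 1.60 against 4.77 ± 0.78 CPM), the basement membrane ligand Egfl6 (66.9 ± 9.40 against 23.5 ± 4.01) and the ubiquitin hydrolase Uchl1 of neurons (19.5 ± 4.63 against 5.17 ± 1.63).

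Lower respiratory chain and absorptive transcripts could come from a lower share of epithelial cells or from RNA of germ cells and epididymis. Loss of Arl13b is the biological explanation that the design gives, and it need not exclude a change in cell shares. With the germ cell score as a covariate the median of the respiratory genes was -0.251 against -0.240 without it (camera, Benjamini-Hochberg adjusted p = 5.59e-20), and that of the transport and brush border genes, 74 together, was -0.209 against -0.184. Both medians met the threshold of 0.05 written in advance for limma's fry. Dilution by germ cell RNA, as far as a mean of log2 CPM tracks it, was therefore argued against as the whole cause of either pattern. The same covariate reduced the number of called genes to 21. No epididymal score was used as a covariate, so RNA of the epididymis was not tested. The share of epithelial cells stays open, and the balance of absorptive and multiciliated cells within the epithelium was not tested. Markers of epithelia, of which 15 were tested, all at 1 CPM or more in every control and 1 of them in another list, had a score that differed by 0.00928 (exact permutation p = 0.944), with Spint2 at 376 against 392 CPM, Epcam at 243 against 254 and Cdh1 at 162 against 177. The respiratory score minus this score differed by -0.239 in cKO, with an exact permutation p of 0.0794, and the transport and brush border score minus it was -0.153, with an exact permutation p of 0.159, while the scores alone had p-values of 0.00794 and 0.0159 in the same test. The epithelial score varied more between libraries than the respiratory score did, which keeps this explanation from being told apart.

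In 100 of the 126 ways to split the 10 libraries into groups of 5, counting the real one, only the real split gave as many called genes (1 of 100; 387 against a highest other of 64). The same held for the 104 higher genes (1 of 100, highest other 36) and for the 283 lower genes (1 of 100, highest other 36). Counts this high were thus rare among splits, and 1 of 100 is the lowest rank that this number allows. The real split also differs in animal numbers (2 control and 4 cKO below 2900, 3 control and 1 cKO above). The rank therefore does not tie the counts to genotype. The number of lists called with a preset correlation was not rare. Of the 100 splits, 18 called at least the 17 lists of the real one, and the highest other called 23.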
